A study of Homo sapiens with 36 samples.

How the data were processed

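RNA from ZR-75-1 cells was labelled as biotinylated cRNA and hybridized to Illumina bead arrays, per the labels' protocols. The authors deposited a table of probe intensity with a detection p-value for every probe and array, per the file headers, in a linear unit that had not been normalized. The authors also deposited a processed intensity table. Tested on the files, each array's column in the processed table was a straight line of the unnormalized intensity, with slopes from 0.324 to 1.573 and medians from 5.4 to 30.9, so that a background had been subtracted and 1 scale applied per array, without a log or quantile step. The deposited detection p-value was used only to infer background, to filter probes and to count the arrays on which a gene was above background.

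The unnormalized intensity of all 36 arrays was processed in R 4.3.3 with limma 3.58.1 and data.table version 1.17.8. Background was fitted by neqc from the detection p-values with an offset of 16, followed by quantile normalization and log2. A probe was kept if its detection p was under 0.05 on at least 4 arrays, which kept 21116 of 48803 probes. Probes were named by the platform annotation joined on probe identifier. Of 27578 probes with 1 symbol, 27541 matched the reference gene table by gene identifier, and 0 symbols changed. Another 13 probes with several symbols and 21212 with none were left out of gene tests. The 4742 kept probes without 1 gene name were tested apart. For each gene the probe with the highest mean over all arrays was used, which gave 12195 genes, 3207 of them with more than 1 kept probe. No genome was at hand, so no coordinates are given. The lowest normalized log2 signal called above background lay between 5.86 and 6.21 per array. A gene was taken as above background on an array (here called measured) if any probe with its symbol was, not only the probe used. Where this held on fewer than all 4 arrays of the dimmer group, the gene's fold is a lower bound. Each array of that group was then taken at its lowest signal above background or at the gene's own signal, whichever is higher. A gene with several probes may thus lie at background on the probe used without a bound. KCNQ3 did so with DHT, at a mean of 5.57 with all 4 arrays counted as measured. An interaction has no such bound, and its fitted size is measured against background where a group lies there.

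Each sample's group was taken from its label, and 0 columns of the tables belonged to other samples. A limma model with 1 mean per group was fitted to all arrays, with 27 residual degrees of freedom, and 18 contrasts were tested with moderated statistics, 3 of them interactions. An adjusted p is Benjamini-Hochberg over all genes tested in 1 comparison, with a threshold of 0.05 and 95% confidence intervals. The number of arrays limits the precision of every value.

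Gene lists, comparisons, the rule for named genes and most alternatives were fixed before the data were examined. The 20 lists are estrogen-induced, androgen-induced and progestin-induced genes, the response that receptors for 3-keto steroids share, steroid receptors and coregulators, steroid conjugation and metabolism, G1/S and DNA replication, G2/M and mitosis, cholesterol synthesis and uptake, fatty acid synthesis and oxidation, luminal and basal epithelial markers, growth factor ligands and receptors, the unfolded protein and amino acid stress response, interferon response, hypoxia and glycolysis, apoptosis regulators, fibroblast and stromal markers, leukocyte and endothelial markers, and housekeeping genes. Of their 532 members 431 were among the genes tested, and 42 symbols stand in more than 1 list. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry.

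The rule for named genes took up to 4 members per list past the threshold in every comparison. It also took up to 6 genes per direction with the largest change past the threshold in some comparisons. These were the comparisons with vehicle or with E2 alone, MPA against PROG, DHT against MPA and the interactions. Except in the interactions, the arrays of those genes did not overlap between the groups. A few fixed genes of steroid response were added in the comparisons with vehicle or with E2 alone. In the remaining comparisons only list members were named, which need not be the largest changes. One fixed gene of the rule is not analysed here. The rule gave 131 genes and 400 pairs of gene and comparison, of which the text prints a part. Genes named outside it are said to be so.

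Shared genes between comparisons with common controls were set beside 100 simulated draws of unchanged groups, independent lists, and the 6 ways to give each comparison its own pair of control arrays. The same was done for E2-responsive genes with the E2 arrays. Other splits of the arrays into groups of the same sizes were refitted, all 35 for a pair of groups and 100 drawn for an interaction. The alternatives tried were log2 and quantile scaling without background correction, the authors' processed values with a floor of 1, no detection filter, a stricter filter (detection p under 0.01 on 18 arrays), the mean of a gene's probes, a fit to the compared groups alone, replicate number as a block, array weights, a robust trended prior, a fold of at least 1.5, and leaving out each array in turn. A block by slide was planned and could not be fitted, as no slide is named. Alternatives with the run of 12 neighbouring columns, with or without vehicle replicate 1, and with 6 runs of 6 columns were added after the data were seen. The closing section gives their effect.

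The method was tested on simulated data with 200 of 12195 genes changed, in 20 draws. For the comparison of DHT with vehicle it recovered 16.0%, 70.9% and 95.3% of genes changed by a log2 of 0.5, 1 and 2. For the interaction of E2 and PROG it recovered 4.48%, 39.3% and 89.0%. No gene had the wrong sign, and the median number of false calls per draw was 1, with at most 53 and 148. A list of 30 genes moved by 0.5 was called in 20 of 20 draws and an unmoved list in 0. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.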

Results

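Gene expression was measured in 36 RNA samples of ZR-75-1, an established human breast cancer cell line that responds to estrogen, on Illumina bead arrays. The samples form 9 groups of 4. Cells received ethanol vehicle, estradiol (E2), dihydrotestosterone (DHT, a potent androgen), medroxyprogesterone acetate (MPA, a synthetic progestin), progesterone (PROG), E2 with DHT, E2 with MPA or E2 with PROG. The ninth group is a further E2 and progesterone treatment that the labels write as E2s+PROG, without saying what the s stands for. Treatment lasted 16 h, after 48 h in medium with 10% hormone-stripped serum, and E2 and DHT were given at 10 nM, alone and together. The labels give no dose for MPA or PROG and none for the E2 given with them, so the E2 dose may differ between E2 alone and the groups of E2 with MPA or PROG. The number of arrays limits the precision, and nothing in the labels says that replicates are separate cultures, so the p-values measure the spread between these samples, which may be technical.

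Between 33.2% and 37.9% of the 48803 probes on an array were above background, and 12195 genes were tested. The median signal per array lay between 121.6 and 247.5. Arrays of 1 group correlated across genes with r between 0.915 and 0.994, where genes are not independent replicates. Differences between replicates were dominated by 1 direction, which held 49.4% of the residual variance. On it, the 12 neighbouring columns 13 to 24 of the deposited table scored between -49.3 and -6.16, and vehicle replicate 1, outside that run, scored -53.8. The run holds 1 vehicle, 2 E2, 3 DHT, 1 E2+DHT, 2 E2+MPA, 2 E2+PROG and 1 E2s+PROG array, and none with MPA or PROG alone. Results inside the run thus rest on a single array for vehicle, E2+DHT and E2s+PROG. Those outside it rest on a single array for DHT, replicate 3, which scored 48.05. On average 34.8% ± 0.87 (SD, n = 12) of probes were above background in the run and 36.4% ± 0.89 (SD, n = 24) outside it. The count of genes in each comparison is therefore also given with the run as a block in the model and within each part that holds its groups. A list call that was lost in any of its 16 alternatives (24 for an interaction) is given with the number in which it held.

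**Figure D1:**
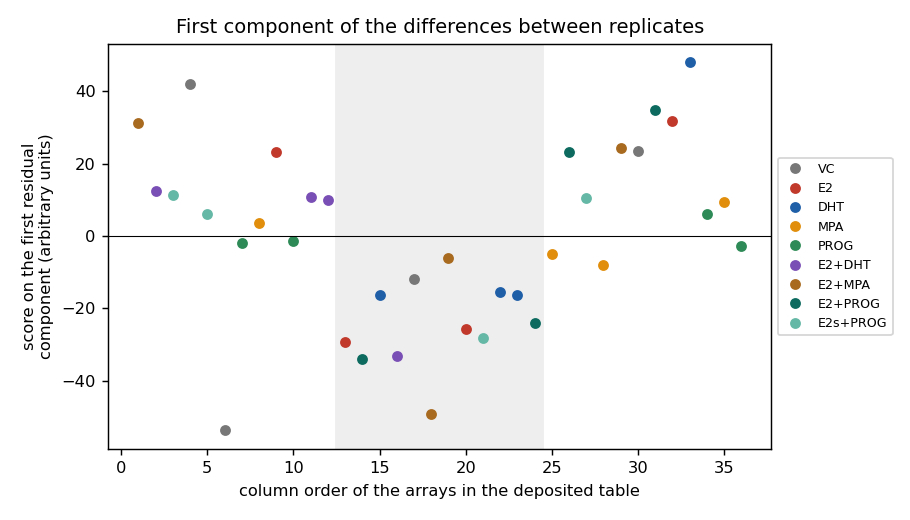
Score of each array (1 point, coloured by group) on the first component of the differences from its group mean, in arbitrary units, against the column order of the arrays in the deposited table. The 12 arrays of the shaded run score between -49.3 and -6.16, and vehicle replicate 1 in column 6 scores -53.8.

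The first question was what E2 changes in cells held without hormone. PDZK1, which encodes a scaffold for membrane transporters, was above background on 1 of 4 vehicle arrays and rose at least 38.4-fold, to a log2 signal of 11.31 ± 0.12 (SD, n = 4) at an adjusted p of 3.35e-23. PGR, the gene of the progesterone receptor, also above background on 1 of 4 vehicle arrays, rose at least 7.55-fold to 8.94 ± 0.36 (SD, n = 4). GREB1, an estrogen-induced growth regulator, measured on 3 of 4 vehicle arrays, rose at least 13.5-fold, and 2 of its 3 probes moved that way. HSPB8, a small heat shock protein, rose 12.1-fold, and KCNH1, a potassium channel measured on 2 of 4 vehicle arrays, at least 9.77-fold. The troponin subunit TNNI2 was above background on 0 vehicle arrays and rose at least 6.03-fold. CLEC3A fell by a log2 of 1.76 on 1 of its 2 probes (0.19 on the other), and ADGRF1, an adhesion receptor measured on 1 of 4 E2 arrays, and COLEC12 and RARRES1, measured on 0, were at least 3.15-fold, 2.41-fold and 2.23-fold lower.

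Of the 36 measured estrogen-induced genes, 21 rose, 0 fell and 15 did not pass, and 24 rose when adjusted over the list alone (limma camera adjusted p = 2.79e-48). Among them IGFBP4, an insulin-like growth factor binding protein, rose 5.01-fold, and TFF1, a secreted trefoil peptide, 3.31-fold. The luminal list of 24 had TFF1 and MYB higher and ELF3 lower, with a list adjusted p of 0.0526. No member of the 33 genes of G1/S and DNA replication passed over all genes, although the list was higher at an adjusted p of 0.0465. That call held in 6 of 16 alternatives, with an adjusted p = 0.561 with an estimated correlation and 0.214 with the run as a block. ESR1, the gene of the estrogen receptor, differed by a log2 of 0.34 with an adjusted p of 0.34. In all, 227 genes passed, 145 higher and 82 lower. Blocking on the run gave 1516, 49.2% of them higher against 63.9%, and 1275 passed in the 24 arrays outside and 30 in the 12 inside the run. The counts of 1516 and 1275 rest in part on vehicle replicate 1, which scores like the run but was taken as outside it. Without that array both were far lower, as the closing section gives. Leaving out vehicle replicate 2 gave 555.

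**Figure D2:**
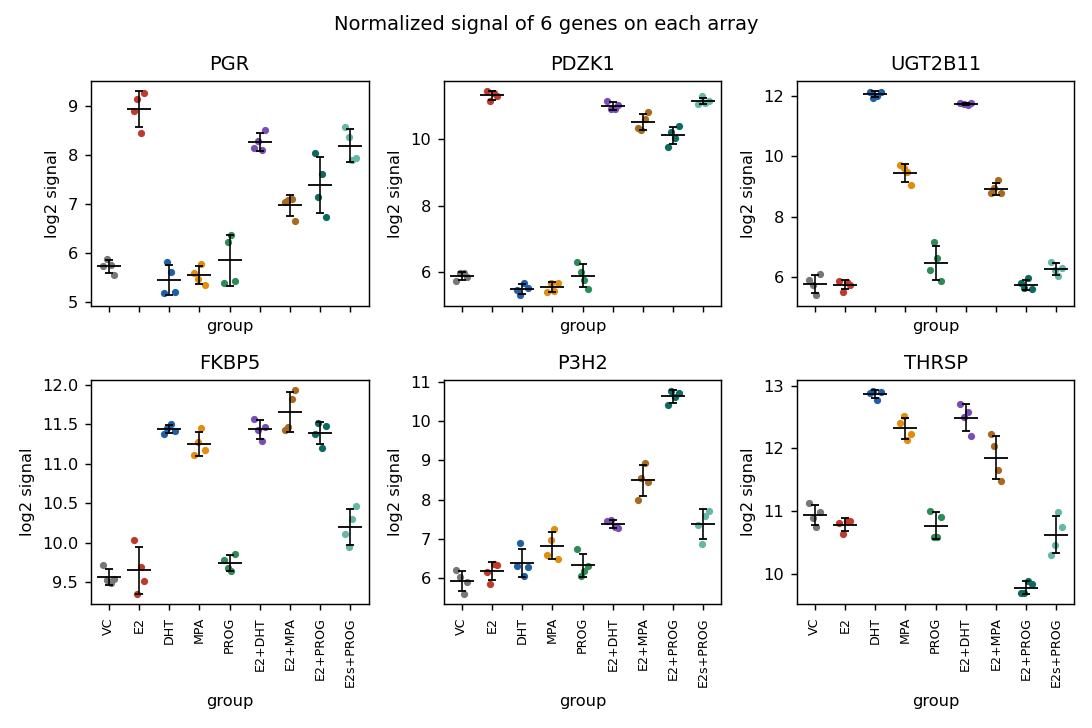
Normalized log2 signal of 6 genes on every array (points), by group, with the mean and SD of 4 arrays (black). FKBP5 lies at 11.44 with DHT, 11.25 with MPA and 9.74 with PROG alone, against 9.57 in vehicle.

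The second question was what the androgen DHT changes. UGT2B11 and UGT2B28, which encode enzymes that attach glucuronic acid to steroids, were above background on 0 vehicle arrays and rose at least 65.3-fold and 41.3-fold, UGT2B11 to 12.05 ± 0.10 (SD, n = 4). UGT2B7, from 6.78 ± 0.90 in vehicle (SD, n = 4), rose 50.8-fold, though its 3 probes moved by a log2 of 0.08 to 5.67, and UGT2B10 rose at least 9.06-fold. These genes are close copies of each other, and how far a probe for 1 copy reads RNA of another is uncertain. FKBP5, a cochaperone of steroid receptors, rose from 9.57 ± 0.10 to 11.44 ± 0.05 (SD, n = 4), 3.65-fold at an adjusted p of 1.14e-11. C1orf116 rose at least 19.4-fold and the chloride exchanger gene SLC26A3 6.91-fold. DOCK2, an activator of Rac, fell from 10.60 ± 0.42 to 7.66 ± 0.13 (SD, n = 4), CBLN2 fell by 1.62, and the cholesterol-esterifying enzyme gene SOAT2, measured on 2 of 4 DHT arrays, was at least 2.9-fold lower.

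Of 26 measured androgen-induced genes, FKBP5, EAF2, STEAP2 and CROT rose and SLC45A3 fell, and 9 rose and 2 fell when adjusted over the list alone (adjusted p = 9.91e-08). Of 19 genes of steroid conjugation and metabolism 8 rose, and 10 rose and 1 fell when adjusted over the list alone (adjusted p = 1.83e-28). FKBP5, CEBPD and NFKBIA rose among 13 genes of the response that receptors for 3-keto steroids share, and 6 when adjusted over the list alone (adjusted p = 2.97e-10). FKBP5, HSD11B2 and S100P rose among 30 progestin-induced genes, 8 rose and 1 fell when adjusted over the list alone (adjusted p = 5.72e-05, but 0.0823 outside the run, the 1 loss in 16). S100P itself passed in 17 of 24 alternatives. The lists of cholesterol synthesis (19 genes, none past the threshold), hypoxia and glycolysis (21 genes, SLC2A3 higher) and leukocyte and endothelial markers (7 genes, VWF at least 3.63-fold higher, with 3 of 4 vehicle arrays above background) were higher at adjusted p of 0.0119, 0.00812 and 0.00409. Adjusted over the list alone 0, 2 and 3 members rose. These calls held in 14, 14 and 15 of 16 alternatives, where the arrays outside the run hold DHT replicate 3 alone of its group. Cholesterol lost its call without vehicle replicate 2 (0.0552) and outside the run (0.0511), hypoxia without vehicle replicate 4 (0.0512) and without DHT replicate 3 (0.122), and the leukocyte and endothelial list outside the run (0.0823). The G1/S list was lower, with a median of -0.27 and an adjusted p of 0.00013, 0 members past the threshold over all genes, and 3 when adjusted over the list alone. Its call held in 15 of 16 alternatives, with adjusted p = 0.135 with an estimated correlation, and its members had a median correlation of -0.59 with the first residual component across arrays, against -0.3 for all genes.

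THRSP, a regulator of lipid synthesis, rose from 10.94 ± 0.16 to 12.86 ± 0.07 (SD, n = 4). PGR (log2 -0.28, adjusted p 0.662), TFF1 (0.06, 0.955) and ESR1 (0.01, 0.99) did not pass. In all, 293 genes passed with DHT, 133 higher and 160 lower. With the run as a block 1010 passed, 33.9% of them higher against 45.4%, and 240 passed outside and 18 inside the run. Outside the run DHT has 1 array, replicate 3, which lay far from the others on the residual component, and inside it vehicle has 1. The block, too, takes vehicle replicate 1 as outside the run. Counts without vehicle replicate 1 and without DHT replicate 1 were 164 and 192.

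The next question was what the synthetic progestin MPA changes. FKBP5 rose 3.21-fold to 11.25 ± 0.15 (SD, n = 4), UGT2B11 and UGT2B28 at least 10.9-fold and 6.11-fold, SLC26A3 6.29-fold and THRSP by a log2 of 1.38. TTC21A and the metalloreductase gene STEAP2 rose at least 3.48-fold and 2.68-fold. AKR1C3, a hydroxysteroid dehydrogenase from a family of close copies, measured on 2 of 4 vehicle arrays, rose at least 2.63-fold. DOCK2 fell by 1.74, CLEC3A by 1.74 on 1 of its 2 probes (0.29 on the other), CBLN2 by 1.68 and BCL2, an inhibitor of cell death, by 1.20. GREB1, measured on 3 of 4 vehicle arrays, rose at least 2.28-fold on the probe used, with 2 of 3 probes moving that way, a call that was lost with log2 and quantile scaling, with the mean of its probes and in a fit to the groups compared alone.

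Among the lists, 7 of 26 androgen-induced genes rose with MPA, 10 rose and 1 fell when adjusted over the list alone (adjusted p = 2.15e-06). Of 30 progestin-induced genes 6 rose, among them HSD11B2, S100P and SGK1 (SGK1 in 17 of 22 alternatives), and 12 rose and 1 fell when adjusted over the list alone (adjusted p = 1.33e-06). The shared 3-keto response had 3 of 13 higher, and 6 when adjusted over the list alone (adjusted p = 3.56e-06), and conjugation 7 of 19, with 10 higher and 1 lower when adjusted over the list alone (adjusted p = 5.28e-15). Fatty acid genes were higher at an adjusted p of 0.0427, with THRSP past the threshold, and 4 higher and 1 lower when adjusted over the list alone. The call held in 12 of 16 alternatives, and was lost without vehicle replicate 2 (0.106), vehicle replicate 4 (0.0576) or MPA replicate 4 (0.0762), and outside the run (0.0577). The G1/S list, with 0 members past the threshold, was lower at an adjusted p of 0.0427, and adjusted p = 0.528 with an estimated correlation, and held in 8 of 16. In all, 229 genes passed, 110 higher and 119 lower. Blocking on the run gave 307, with 694 in the arrays outside the run, which holds no MPA array. The count was 1692 without vehicle replicate 2, 119 without vehicle replicate 1 and 126 without MPA replicate 3. The median gene differed by -0.105, but by 0.025 on the authors' processed values, on which 65.3% of the genes past the threshold were higher against 48.0%.

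Progesterone alone moved few genes past the threshold. The secretoglobin gene SCGB1D2 rose from 12.86 ± 0.28 to 13.88 ± 0.13 (SD, n = 4), C1orf116 (by a log2 of 0.22 on its other probe) and TTC21A rose at least 1.86-fold and 1.44-fold, and the serpin gene SERPINA3 from 7.43 ± 0.79 to 8.83 ± 0.27, with vehicle replicate 1 among the PROG arrays. HTRA1, a serine protease measured on 3 of 4 PROG arrays, was at least 2.01-fold lower, and NAV1 and COLEC12 fell by 0.95 and 0.90. These are the 7 genes past the threshold, 4 higher and 3 lower. TTC21A, HTRA1, NAV1 and COLEC12 passed in 11 of 23, 12 of 22, 12 of 23 and 10 of 22 alternatives. SERPINA3 was named after its values were seen. FKBP5 differed by 0.17 (adjusted p 0.402) at 9.74 ± 0.10, PGR by 0.12 and TFF1 by 0.10. No list member passed over all genes, and 2873 genes had an unadjusted p under 0.05. The conjugation list was higher at an adjusted p of 0.0141, with 4 of 19 higher when adjusted over the list alone, and adjusted p = 0.086 with an estimated correlation, a call that held in 10 of 16 alternatives. The count rests on single vehicle arrays. It was 943 without vehicle replicate 2, 64 without replicate 4, 3 without replicate 1 and 1 without replicate 3. It was also 3, 3, 3 and 4 without PROG replicates 1, 2, 3 and 4. The block for the run gave 9 genes, 4 when vehicle replicate 1 was left out as well, and 727 in the arrays outside the run.

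Genes that DHT and MPA shared were counted against the same vehicle arrays. Of 293 and 229 genes, 103 passed in both in the same direction, 56 higher and 47 lower, and no gene passed in opposite directions. Independent lists would share 2.76, and simulated unchanged groups with the same vehicle arrays shared at most 1 in 100 draws. With separate vehicle arrays for each steroid the shared genes numbered 40 to 59 over 6 splits, and 212 with the run as a block. The correlation of the changes across all genes was 0.618, inside the range of -0.264 to 0.907 that shared vehicle arrays alone gave, so it does not by itself show a common response. All 7 progesterone genes passed the same way with MPA, where independent lists would share 0.0654, simulated groups at most 0, and separate vehicle arrays gave 1 to 20, and the block 9. E2 and DHT shared 16 genes in 1 direction and had 2 opposite, with 5 to 12 on separate arrays, and E2 and MPA shared 27 with 4 opposite, and 8 to 20 on separate arrays. With the block, which takes vehicle replicate 1 as outside the run, those became 357 and 119. DHT and PROG shared 5, with 0 to 14 on separate arrays and 6 with the block, and E2 and PROG 2, with 1 to 9 and 2. For these 4 pairs in turn independent lists would share 2.66, 2.11, 0.083 and 0.0677, and simulated groups shared at most 69, 1, 663 and 1.

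When DHT was added to E2, UGT2B11 and UGT2B28 rose at least 53.8-fold and 37.4-fold over E2, C1orf116, measured on 1 of 4 E2 arrays, at least 23.2-fold and FKBP5 by a log2 of 1.79, from 9.65 ± 0.29 to 11.44 ± 0.12 (SD, n = 4). CLDN8, a tight junction protein, rose from 8.36 ± 0.18 to 11.06 ± 0.13 (SD, n = 4). DOCK2 fell by 3.00 and CBLN2 by 1.97, and LMO1 and the chemokine gene CXCL12, each measured on 2 of 4 E2+DHT arrays, were at least 2.88-fold and 2.26-fold lower. Of 26 androgen-induced genes 6 rose (9 higher and 1 lower when adjusted over the list alone, adjusted p = 7.39e-12). Progestin-induced genes had 5 of 30 higher (6 when adjusted over the list alone, adjusted p = 1e-09), the shared 3-keto response 5 of 13 (6 when adjusted over the list alone, adjusted p = 1.85e-13) and conjugation 6 of 19 (9 when adjusted over the list alone, adjusted p = 7.99e-30). In the fatty acid list THRSP and ACACA rose (ACACA in 19 of 24 alternatives), also when adjusted over the list alone (adjusted p = 0.000518). Hypoxia genes, 0 of which passed alone, were higher at an adjusted p of 0.001. The leukocyte and endothelial list, with VWF higher, had an adjusted p of 0.0434, and adjusted p = 0.0602 with an estimated correlation, and held in 7 of 16 alternatives. The G1/S list was lower (adjusted p = 0.00016), with adjusted p = 0.157 with an estimated correlation and 0.0624 by fry, and held in 14 of 16. Its members had a median correlation of -0.59 with the first residual component, against -0.3 for all genes. PGR differed from E2 alone by -0.68 with an adjusted p of 0.315. In all, 132 genes passed, 104 higher and 28 lower, with 159 with the run as a block, 84 outside and 14 inside the run.

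Added to E2, MPA lowered a part of the estrogen-induced genes. PGR fell from 8.94 ± 0.36 to 6.97 ± 0.21 (SD, n = 4), and TFF1 by 1.24, while CXCL12 and KCNK5, each measured on 1 of 4 E2+MPA arrays, were at least 2.22-fold and 1.7-fold lower. The TFF1 call was lost in the arrays outside the run. Of 36 estrogen-induced genes 8 fell and 0 rose, and 12 fell when adjusted over the list alone (adjusted p = 2.85e-06). TUBA3E, a tubulin gene with close copies, measured on 3 of 4 E2 arrays, rose at least 10.2-fold to 10.00 ± 0.08 (SD, n = 4). FKBP5, EHF and HSD11B2 rose by 2.01, 1.78 and 1.22, and UGT2B11 and STAT5A, measured on 0 and 1 of 4 E2 arrays, at least 7.7-fold and 2.33-fold. Of the other lists, 8 of 26 androgen-induced genes rose (9 higher and 1 lower when adjusted over the list alone, adjusted p = 9.16e-08), 8 of 30 progestin-induced (9 when adjusted over the list alone, adjusted p = 1.62e-09), 5 of 13 of the shared response (7 higher and 1 lower when adjusted over the list alone, adjusted p = 1.62e-09) and 6 of 19 of conjugation (6 when adjusted over the list alone, adjusted p = 1.79e-09). Of 9 receptors and coregulators PGR fell, 1 rose and 3 fell when adjusted over the list alone (adjusted p = 0.00931). That call held in 14 of 16 alternatives, and was lost without E2 replicate 1 (0.0544) and without E2+MPA replicate 2 (0.0583). Fatty acid genes (THRSP past the threshold, 2 higher and 1 lower when adjusted over the list alone) and hypoxia genes (0 past it either way) were higher at adjusted p of 0.0209 and 0.0116. They held in 13 and 14 of 16, and both calls were lost outside the run (0.0635 and 0.135) and without E2 replicate 1 (0.0544 and 0.101), and the fatty acid call without E2+MPA replicate 2 (0.0592). BCL2 fell by 1.27, and ESR1 differed by -0.56 with an adjusted p of 0.089. In all, 261 genes passed, 150 higher and 111 lower. The block for the run gave 523, with 88 outside and 588 inside the run. The count was 733, 514, 163 and 156 without E2+MPA replicates 1 to 4 in turn, and 162 without E2 replicate 2. On the authors' processed values 71.9% were higher against 57.5%.

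Added to E2, progesterone changed a wide set of genes. P3H2, a collagen-modifying enzyme, measured on 3 of 4 E2 arrays, rose at least 21.5-fold to 10.63 ± 0.16 (SD, n = 4), C1orf116, measured on 1 of 4, at least 21.6-fold, and the neuronal secreted protein gene NELL2 by a log2 of 3.80. PHACTR3 and the actin-binding CALD1 rose at least 9.32-fold and 6.82-fold. AKR1C3, measured on 3 of 4 E2 arrays, rose at least 8.84-fold to 9.66 ± 0.15 and HSD11B2, which inactivates cortisol, from 8.74 ± 0.11 to 10.74 ± 0.16 (SD, n = 4). FKBP5 rose by 1.74, and the metallothionein MT2A and the fatty acid desaturases FADS1 and FADS2, each from a family of close copies, by 1.75, 1.92 and 1.62. ESR1 fell from 11.11 ± 0.07 to 10.08 ± 0.21 and PGR from 8.94 ± 0.36 to 7.39 ± 0.57 (SD, n = 4), KCNH1 by 2.08, PIP by 1.40, PDZK1 by 1.20 and THRSP by 1.01.

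Of 30 progestin-induced genes 10 rose and 0 fell with E2+PROG, 13 rose and 1 fell when adjusted over the list alone (adjusted p = 4.26e-18). The shared 3-keto response had 6 of 13 higher, and 9 when adjusted over the list alone (adjusted p = 1.86e-15). Of 16 basal epithelial markers CAV1, CAV2, LAMB3 and KRT23 rose, 6 when adjusted over the list alone (adjusted p = 6.96e-06), with KRT23 past the threshold in 17 of 24 alternatives. CAV1 was above background on 0 E2 arrays, rose at least 1.25-fold, and lost its call without the detection filter. Estrogen-induced genes moved both ways, 3 higher and 7 lower (adjusted p = 0.001, lower), and 4 and 9 when adjusted over the list alone. The call held in 14 of 16 alternatives, and was lost on the authors' processed values (0.0516) and outside the run (0.0643). Androgen-induced genes had 3 higher and PIP lower (adjusted p = 0.001), 6 and 2 when adjusted over the list alone. Receptors and coregulators had ESR1 and PGR lower (adjusted p = 0.00058), conjugation 3 higher, 4 when adjusted over the list alone (adjusted p = 2.57e-06), and hypoxia PFKFB3 higher, 2 when adjusted over the list alone (adjusted p = 0.0125). The hypoxia call held in 13 of 16 alternatives, and was lost without E2 replicate 1 (0.155), E2+PROG replicate 1 (0.0689) or E2+PROG replicate 3 (0.0547). The fatty acid list had 2 higher and 2 lower (adjusted p = 0.984), and the luminal list 2 higher and 4 lower without a list call. In all, 306 genes passed, 227 higher and 79 lower. The block gave 405, with 133 outside and 89 inside the run.

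**Figure D3:**
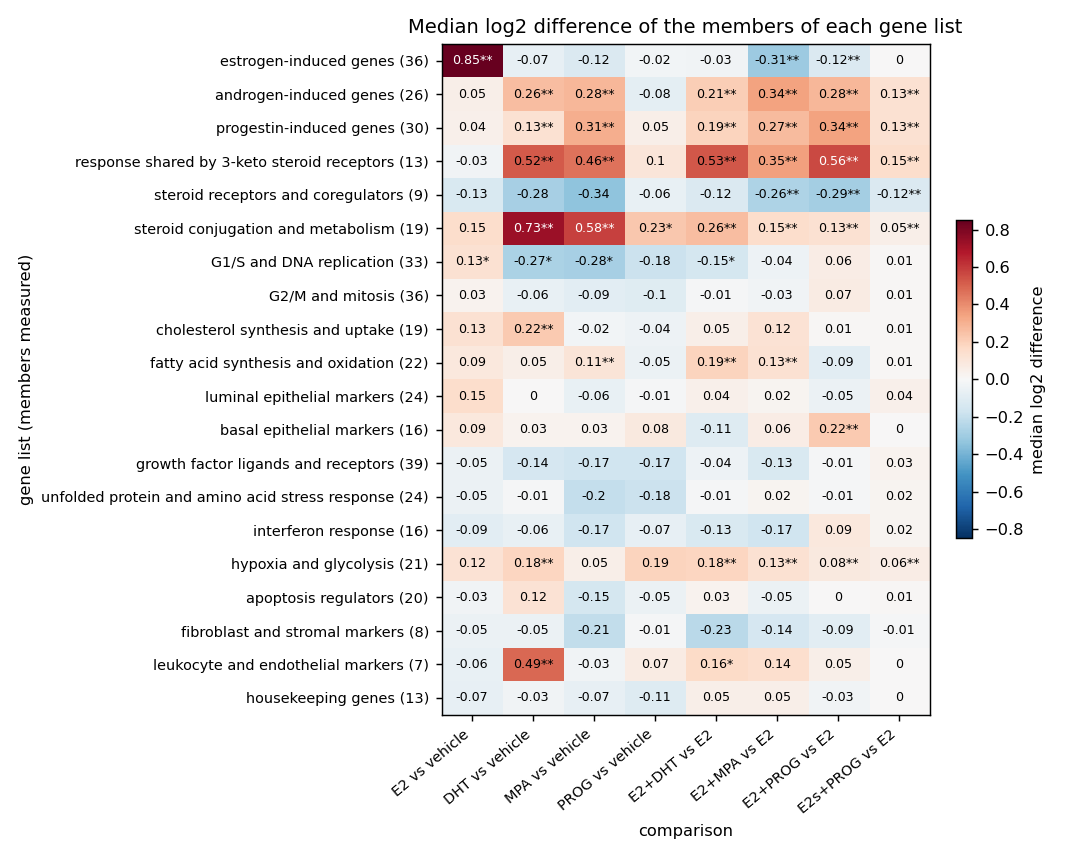
Median log2 difference over the measured members of each gene list (lines, with their number) in 8 comparisons (columns); 1 asterisk marks an adjusted p under 0.05 by camera, 2 asterisks one that holds with an estimated correlation as well. Estrogen-induced genes have a median of 0.85 with E2, and the shared 3-keto response one of 0.56 when progesterone is added to E2.

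Whether a steroid changed a gene differently with and without E2 was tested as an interaction. For progesterone 188 genes passed, 165 higher and 23 lower, against 8 for MPA and 1 for DHT. The difference between these interactions was not tested, and an E2 dose that differs between the groups would enter those of progesterone and MPA. Among genes above background on all arrays of the 4 groups, NELL2 rose by 3.57 more with E2 than without, FADS1 by 1.93, FKBP5 by 1.57 (95% CI 1.18 to 1.96, adjusted p 1.62e-06) and HSD11B2 by 1.54, and PIP and ESR1 had interactions of -2.10 and -1.15. P3H2, PHACTR3, AKR1C2, PGR and PDZK1 passed as well, but some of their groups lay at background, and the fitted size is then no bound on the change. For MPA, LGR4 (1.59) was higher and SSTR2 (-1.26) and UROD (-0.81) lower, and TUBA3E, P3H2, ODAD3, PGR and CXCL12 passed with groups at background. LGR4, SSTR2 and UROD passed in 12, 18 and 16 of 31 alternatives, P3H2 and PGR in 11 and 20 of 30. The single gene for DHT was CXCL12 (adjusted p 0.028), above background on 4 of 4 E2 arrays and on 0, 1 and 2 with vehicle, DHT and E2+DHT, and past the threshold in 9 of 31 alternatives, with 667 genes at an unadjusted p under 0.05. Of 30 progestin-induced genes 7 passed the progesterone interaction, 13 higher and 1 lower when adjusted over the list alone (adjusted p = 6.43e-05), and of 13 in the shared response 3, 8 when adjusted over the list alone (adjusted p = 9.16e-05). The estrogen-induced and basal lists had adjusted p of 0.0259 each, and adjusted p = 0.0643 with an estimated correlation for each, and held in 18 and 15 of 24 alternatives. For MPA the estrogen-induced list had 0.0157, with adjusted p = 0.0773 with an estimated correlation, and held in 19 of 24. For DHT the conjugation list had 0.0122, with adjusted p = 0.0788 with an estimated correlation, and held in 15 of 24. With the run as a block 435, 80 and 0 genes passed for progesterone, MPA and DHT, 68.5% of the first higher against 87.8%, and 174, 1 and 1 outside the run. Inside it DHT had 0, and no value can be had for progesterone or MPA. The limma counts of 0 for DHT stood beside 1986 genes at an unadjusted p under 0.05 with the block and 176 inside the run. The progesterone count was 393 without vehicle replicate 2, 345 without E2 replicate 1, 123 without E2 replicate 4 and 116 without E2+PROG replicate 2. The MPA count was 955 without vehicle replicate 2, 748 and 482 without E2+MPA replicates 1 and 2, 26 without E2 replicate 1, and 3 without vehicle replicate 1, E2 replicate 2 or MPA replicate 1.

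A related question is how far a second steroid turns back the E2 response. Of the 227 E2-responsive genes, MPA moved 42 against the E2 change (here called back), 33 that E2 raised and 9 that it lowered, and 8 further away. Progesterone moved 41 back, 27 raised and 14 lowered by E2, and 23 further, and DHT moved 6 back and 7 further. Back does not mean to the vehicle level, as most of the E2-lowered genes moved back by MPA or progesterone went past it. NELL2 changed by -0.78 with E2, then by 3.80 with progesterone and 1.43 with MPA, and KRT80 by -0.91, then 1.85 and 0.97. Others stopped short of it, such as LGR4 with MPA (-0.93, then 0.86). Of the 227 genes 25 were moved back by both MPA and progesterone and 5 by all 3. Since the E2 arrays stand in both contrasts, the E2 arrays were also divided, which left 13 to 29 moved back for MPA, 15 to 27 for progesterone and 1 to 4 for DHT. In 100 draws of simulated unchanged groups at most 0, 374 and 6 genes moved back for MPA, progesterone and DHT. With the run as a block 1516 genes responded to E2, of which MPA moved back 163, progesterone 87 and DHT 23. That block takes vehicle replicate 1 as outside the run, and without this array far fewer genes responded to E2.

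The E2s+PROG group lay between E2 and E2+PROG, nearer to E2. Against E2, KCNQ3 rose by 1.22 on 1 of its 2 probes (-0.12 on the other), SYBU by 1.21 and HSD11B2 by 0.75 to 9.50 ± 0.13 (SD, n = 4). TUBA3E, C1orf116 and P3H2, measured on 3, 1 and 3 of 4 E2 arrays, rose at least 4.59-fold, 2.62-fold and 2.26-fold, P3H2 to 7.38 ± 0.37 (SD, n = 4), and CXCL12, measured on 3 of 4 E2s+PROG arrays, was at least 1.99-fold lower. P3H2 and CXCL12 passed in 18 and 17 of 23 alternatives. PNMT, which makes adrenaline, rose at least 1.62-fold. In all, 11 genes passed, 10 higher and 1 lower, with 15 with the run as a block and 5 outside the run. Inside it limma called 0, with 202 genes at an unadjusted p under 0.05 and 1 array of E2s+PROG. FKBP5 differed from E2 by 0.55 with an adjusted p of 0.186. Progestin-induced genes (HSD11B2 higher, 2 when adjusted over the list alone), androgen-induced genes, the shared response, conjugation and hypoxia were higher at adjusted p of 0.00019, 0.001, 0.000102, 0.00126 and 0.0117, and receptors and coregulators lower at 0.00282. HSD11B2 was the only member of these lists past the threshold over all genes. The test fry, which asks whether a list moves on balance, called none of the lists. In the same order the calls held in 15, 15, 15, 14, 9 and 13 of 16 alternatives, and conjugation, hypoxia and receptors lost theirs outside the run (0.327, 0.392 and 0.186).

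Against E2+PROG, 212 genes passed in E2s+PROG, 47 higher and 165 lower. AKR1C2 and STAT5A, measured on 0 and 3 of 4 E2s+PROG arrays, were at least 9.3-fold and 2.32-fold lower, and AKR1C3, MT2A, FADS1, HSD11B2 and FKBP5 differed by -2.79, -1.52, -1.43, -1.24 and -1.19. PIP, PDZK1, ESR1 and THRSP were higher by 1.91, 1.03, 0.94 and 0.85. Progestin-induced genes had 7 of 30 lower, 11 when adjusted over the list alone (adjusted p = 2.73e-15), the shared response 3 of 13, 8 when adjusted over the list alone (adjusted p = 4.23e-11), basal markers 3 of 16, 5 when adjusted over the list alone (adjusted p = 4.15e-06), and conjugation 3 of 19, also 3 with 1 higher when adjusted over the list alone (adjusted p = 0.000402). Estrogen-induced genes had 4 higher and 1 lower, 6 and 2 when adjusted over the list alone (adjusted p = 0.00779), a call lost on the authors' processed values (0.0588) and outside the run (0.075) and held in 14 of 16 alternatives. The block gave 245, with 109 outside and 41 inside the run. Without E2+PROG replicate 4 the count was 137.

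The steroids themselves were compared next. DHT was given at 10 nM, and as the doses of MPA and PROG are not given, they may differ. MPA exceeded PROG in UGT2B7 by 3.07, SLC26A3 by 1.66, THRSP by 1.55, FKBP5 by 1.51 (95% CI 1.24 to 1.79) and HSD11B2 by 0.81, and was lower in CBLN2 by -1.31 and DOCK2 by -1.23. The 3 probes of UGT2B7 differed by 0.05 to 3.07. In this comparison 56 genes passed, 53 higher and 3 lower, with 87 with the run as a block and 75 outside it. Conjugation had 6 of 19 higher, 7 when adjusted over the list alone (adjusted p = 4.59e-26), and androgen-induced genes 4 of 26, 5 when adjusted over the list alone (adjusted p = 1.08e-13). Progestin-induced genes had 3 of 30, 6 when adjusted over the list alone (adjusted p = 9.47e-12), the shared response 2 of 13, 4 when adjusted over the list alone (adjusted p = 3.07e-11), and fatty acids THRSP (adjusted p = 0.019). The fatty acid call held in 13 of 16 alternatives, and was lost on the authors' processed values (0.202), without MPA replicate 4 (0.0978) and outside the run (0.0541). The G1/S list was lower at an adjusted p of 0.00443, with no member past the threshold over all genes. It had an adjusted p = 0.293 with an estimated correlation and 0.395 by fry, and held in 14 of 16. Of the 229 genes past the threshold against vehicle with either steroid, 50 differed and 150 had a 95% CI of the difference within a log2 of 1 on either side. Of all genes tested, 92.6% had such an interval. A log2 of 1 is more than the median change of genes past the threshold against vehicle, 1.85-fold with MPA and 1.755-fold with DHT. Such an interval therefore does not show that 2 steroids act alike on a gene.

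DHT exceeded MPA in UGT2B28 by 2.76, UGT2B10 by 2.57 and ADH1C, an alcohol dehydrogenase, by 2.13, and VWF, measured on 2 of 4 MPA arrays, was at least 4.35-fold higher. DHT was lower in SERPINA3 by -1.69 and DOCK2 by -1.20, and PSCA and PNMT, measured on 1 and 0 of 4 DHT arrays, were at least 2.89-fold and 2.41-fold lower. Here 38 genes passed, 26 higher and 12 lower, with 35 with the run as a block and 13 outside it, and 77 without DHT replicate 3. Outside the run DHT has 1 array, replicate 3, here and in the comparison with PROG. On the authors' processed values 47.8% of the genes past the threshold for DHT against MPA were higher against 68.4%. Conjugation had 4 of 19 higher, 6 higher and 1 lower when adjusted over the list alone (adjusted p = 1.66e-07). Of 419 genes responsive to either, 33 differed and 337 had an interval within a log2 of 1. DHT exceeded PROG in UGT2B7 by 5.70, THRSP by 2.10 and FKBP5 by 1.69, and UGT2B28 and VWF, measured on 1 and 0 of 4 PROG arrays, were at least 43.5-fold and 4.9-fold higher. The 3 probes of UGT2B7 differed by 0.12 to 5.70. There 168 genes passed, 135 higher and 33 lower, with 125 with the run as a block and 28 outside it, 771 without DHT replicate 3 and 110 without PROG replicate 2. Conjugation (7 of 19, 11 when adjusted over the list alone), the shared response (3 of 13, 6 when adjusted over the list alone) and androgen-induced genes (4 of 26, 8 higher and 1 lower when adjusted over the list alone) had adjusted p of 1.7e-17, 1.19e-06 and 8.26e-05. Progestin-induced genes had an adjusted p of 0.0275, and adjusted p = 0.226 with an estimated correlation, and G1/S genes were lower at 0.00622, with adjusted p = 0.376 with an estimated correlation and 0.254 by fry. They held in 12 and 13 of 16 alternatives. Of 295 responsive genes 100 differed and 187 had an interval within a log2 of 1, as had 84.3% of all genes.

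With E2 present, E2+MPA and E2+PROG differed in 296 genes, 94 higher and 202 lower with MPA. THRSP was higher by 2.08 and PIP by 1.33, and UGT2B11 and STEAP2, measured on 2 and 0 of 4 E2+PROG arrays, at least 7.61-fold and 3.16-fold. AKR1C2, measured on 1 of 4 E2+MPA arrays, was at least 8.5-fold lower, and MT1X, MT2A, CCN5, FADS1 and TFF1 differed by -1.82, -1.76, -1.25, -1.18 and -1.13, TFF1 past the threshold in 18 of 24 alternatives. Androgen-induced (adjusted p = 0.0217, adjusted p = 0.0772 with an estimated correlation), basal (adjusted p = 0.0156, adjusted p = 0.0772 with an estimated correlation) and interferon lists (adjusted p = 0.0156, adjusted p = 0.168 with an estimated correlation) lost their calls there and held in 12, 13 and 13 of 16 alternatives. The block gave 400 genes, with 91 outside and 526 inside the run, and 192 without E2+PROG replicate 4. E2+DHT and E2+MPA differed in 64 genes, 28 higher and 36 lower with DHT, among them UGT2B28 (3.16), PGR (1.29) and STEAP2 (-1.48). VWF, measured on 2 of 4 E2+MPA arrays, was at least 4.74-fold higher, and STAT5A, measured on 0 E2+DHT arrays, at least 2.43-fold lower. Estrogen-induced genes had 3 of 36 higher with DHT, 7 when adjusted over the list alone (adjusted p = 6.84e-05), and conjugation 4 of 19, 4 higher and 1 lower when adjusted over the list alone (adjusted p = 1.74e-10). Receptors (0.0169, adjusted p = 0.0662 with an estimated correlation) and G1/S genes (0.0025, adjusted p = 0.382 with an estimated correlation) lost their calls there and held in 11 of 16 alternatives each. The block gave 81, with 33 outside and 79 inside the run.

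E2+DHT and E2+PROG differed in 401 genes, 151 higher and 250 lower with DHT. THRSP was higher by 2.72, EAF2 by 1.91, PIP by 1.44, ESR1 by 0.77 and UGT2B11, measured on 2 of 4 E2+PROG arrays, at least 53.2-fold, while WNT4, a secreted signal of breast development, FADS1 and MT2A differed by -1.69, -1.63 and -1.58. STAT5A and CAV1, measured on 0 E2+DHT arrays, were at least 2.64-fold and 1.28-fold lower, and 5 of 16 basal markers were lower, also when adjusted over the list alone (adjusted p = 6.53e-05). Conjugation moved both ways, 5 higher and 3 lower, 7 and 5 when adjusted over the list alone (adjusted p = 0.00254). Progestin-induced genes (0.00155, adjusted p = 0.0573 with an estimated correlation), receptors (0.0121, adjusted p = 0.0573 with an estimated correlation), G1/S genes (0.000122, adjusted p = 0.143 with an estimated correlation) and interferon genes (0.0188, adjusted p = 0.173 with an estimated correlation) lost their calls there and held in 15, 14, 15 and 15 of 16 alternatives. The block gave 470 genes, with 237 outside and 65 inside the run. Of the genes responsive to either steroid of a pair, 256 of 463, 218 of 318 and 155 of 398 had an interval within a log2 of 1 for MPA with PROG, DHT with MPA and DHT with PROG. Of all genes, 87.65%, 88.81% and 86.73% had one, so these counts do not show alike responses.

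**Figure D4:**
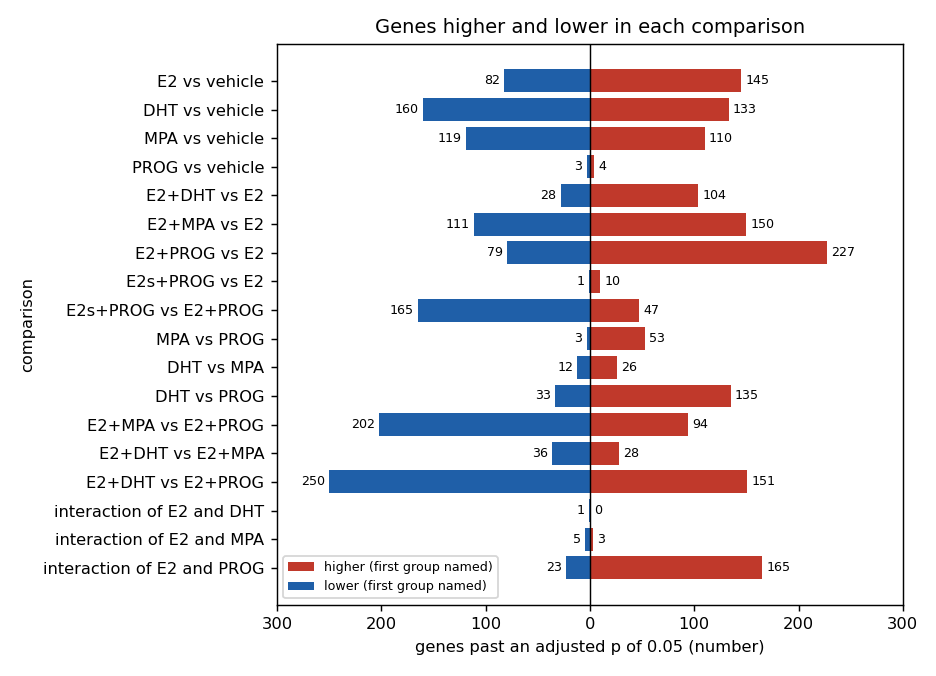
Number of genes past an adjusted p of 0.05 in each comparison, higher (red, to the right) and lower (blue, to the left) in the first group named. For an interaction, higher means that the signed log2 change by the second steroid was more positive with E2 than without, whatever its size. The counts run from 1 for the interaction of E2 and DHT to 401 for E2+DHT against E2+PROG.

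Some lists had no call in any of the 18 comparisons. The lowest adjusted p was 0.0526, with E2, for the 24 luminal markers, 0.0937 for the 36 genes of G2/M and mitosis, 0.117 for the 39 growth factor ligands and receptors, 0.108 for the 8 fibroblast and stromal markers and 0.277 for the 24 genes of the unfolded protein and amino acid stress response. It was 0.443 for the 20 apoptosis regulators and 0.291 for the 13 housekeeping genes. Of the 83 list calls made with a preset correlation, 61 held with an estimated one.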

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

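Both tests with the run of columns as a block, both tests of the residual component and the share of E2s+PROG beside other responses were chosen only after the result was seen.

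A first pattern is that progesterone changed 188 genes differently with and without E2, where MPA did so for 8 and DHT for 1, though without vehicle replicate 2 the counts were 393 for progesterone and 955 for MPA, and the difference between the steroids was not tested. With the run of columns as a block and vehicle replicate 1 left out, 163 of the 188 genes stayed past the threshold, which argues against the run as the whole cause. Progesterone arrays that had received no steroid are argued against by their place between vehicle and E2+PROG. Over the genes of E2+PROG against E2 they moved by 0.091 of that difference, all above the vehicle arrays, with an exact two-sided permutation p of 0.0286, the smallest that 4 and 4 arrays can give. Single vehicle arrays ran from 0.004 to 0.1 on this score. DHT alone scored 0.205 against 0.136 for PROG, so the score is not particular to progesterone. A candidate explanation, as a hypothesis found and tested on the same data, is that E2 supplies the progesterone receptor, since the genes of the interaction had a median E2 and MPA interaction of at least 0.238 over 6 splits, against -0.182 to 0.168 for DHT, but with the run and vehicle replicate 1 as a block MPA had 0.196 to 0.403 and DHT 0.156 to 0.248, and the data cannot tell, while a dose of E2 or progesterone or a loss of progesterone before sampling stays open and untested.

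A second pattern is the direction shared by the 12 neighbouring columns and vehicle replicate 1. The largest difference between 12 neighbouring columns and the rest was 36.29, with a permutation p of 4e-05 over orders of the columns, which argues against a chance order. The score rose with the share of probes above background, less its group mean, with r of 0.711 and rho of 0.697 (permutation p of 1e-05 each, the smallest that 100000 permutations can give), and r of 0.662 without the 2 farthest arrays. Outside the run r was 0.645 and inside it 0.252. Lower RNA or labelling yield was not measured and stays open. Among the run arrays and vehicle replicate 1, the median signal ran from 121.9 on vehicle replicate 1 to 223.4 on E2 replicate 1. Over all arrays it ran from 121.6 to 247.5, so the signal does not by itself show a lower yield. Which step differed stays open, as nothing names a slide or a day, and no biological explanation was tested.

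Another pattern is that E2s+PROG lay nearer to E2 than to E2+PROG. It moved by at least 0.151 of the E2+PROG response over 6 splits of the E2 arrays, which argues against E2 alone. All E2 arrays had helped choose the genes, though, which can raise that share, and vehicle scored 0.045 on that response. E2+DHT, without progesterone, scored 0.199 on it against 0.21 for E2s+PROG. Fitted beside the E2+MPA and E2+DHT responses, the progesterone share was 0.024 to 0.129. The E2+MPA share was 0.258 to 0.364 and the E2+DHT share -0.205 to -0.076. These responses were fitted together against the same E2 arrays, and DHT and MPA share genes, so the negative share cannot decide on DHT. The data cannot tell whether the arrays had progesterone, MPA, DHT or a further steroid. A mixture of E2 and E2+PROG RNA predicts 1 share for every gene, but shares from separate sets of the arrays had a mean correlation of 0.381 across 106 genes, from 0.052 to 0.621 over the ways to divide them. That argues against a plain mixture, though compression of the array signal could give such shares too and was not tested. A biological difference in the E2s treatment stays open, as neither its meaning nor its E2 dose is in the labels.

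Among 75 groups of 4 values, 48 of gene levels and 27 of array measures, 9 had an array far from the others, and chance gives about 1 in 20. The log2 signal of PGR was 6.66 on E2+MPA replicate 4, with the others from 7.04 to 7.11. The log2 signal of AKR1C3 was 9.43 on E2+PROG replicate 1, with the others from 9.72 to 9.76, and that of HSD11B2 was 9.29 on E2s+PROG replicate 1, with the others from 9.55 to 9.57. The log2 signal of SERPINA3 was 8.61 on vehicle replicate 1, with the others from 6.96 to 7.17. The share of probes above background was 35.18% on MPA replicate 2, with the others from 36.42% to 36.64%. On the residual component DHT replicate 3 scored 48.05 (others -16.41 to -15.4), PROG replicate 1 5.963 (others -2.748 to -1.338), E2+DHT replicate 1 -33.19 (others 9.836 to 12.52) and E2s+PROG replicate 4 -28.28 (others 6.223 to 11.43).

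A difference between the effect with and without E2, by the interaction test, singled out further genes. For DHT it was CXCL12 (-1.47). For MPA these were TUBA3E (2.70), LGR4 (1.59), P3H2 (1.42), ODAD3 (-2.34), PGR (-1.79), CXCL12 (-1.49), SSTR2 (-1.26) and UROD (-0.81). For progesterone they were P3H2 (4.06), PHACTR3 (3.83), NELL2 (3.57), C1orf116 (3.48), CALD1 (3.17), AKR1C2 (3.16), PIP (-2.10), SFPQ (-1.90), AHSA2P (-1.86), BPIFB1 (-1.74), PGR (-1.68) and KCNH1 (-1.64), with SFPQ past the threshold in 10 of 31 alternatives and AHSA2P in 23 of 31. All are differences of log2 changes. Only NELL2, PIP, BPIFB1, LGR4, SSTR2 and UROD were above background on all arrays of their 4 groups, and for the others the fitted size is measured in part against background and is no bound on the change.

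Of 4742 probes above background that carry no single gene name, 29 passed the threshold with E2, 18 with DHT, 36 with MPA and 5 with PROG, each against vehicle.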

How the results depend on the processing

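Every alternative with the run of columns, with or without vehicle replicate 1, or with 6 runs was added after the data were seen, and the others, each array left out in turn among them, were planned. Of 6150 results for single genes under the alternatives, 5406 kept their side of the threshold, 691 lost the call, 26 gained one, 27 moved and 0 reversed. Leaving out single arrays gave 3528 more, of which 3128 kept their side, 384 lost the call and 0 reversed. Of 83 list calls 61 held with an estimated correlation, 71 by fry, 74 on the authors' processed values, 77 without the filter, 79 with the run as a block and 60 in the arrays outside it. Replicate numbers do not pair the arrays (mean r of 0.0086 between arrays of 1 number), and as a block they left 82 of the 83 list calls and moved no comparison's count by over 1.5 times. A block by slide was not run, as no slide is named. The signal over background limits genes near the limit of detection, for which only bounds are given where a gene was not measured on every array of the dimmer group. Where arrays are left out, the cause of a lower count is in part the smaller number of arrays, and a lone array is assumed to vary like the other groups. For the other alternatives the cause was not tested.

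In the order E2, DHT, MPA and PROG against vehicle, then E2+DHT, E2+MPA and E2+PROG against E2, a fit to the compared groups alone gave 67, 34, 40, 2, 56, 68 and 144 genes. It gave 7 for E2s+PROG against E2 and 137 against E2+PROG, 17 for DHT against MPA and 102 for DHT against PROG. With E2, it gave 82 for MPA against PROG, 27 for DHT against MPA and 241 for DHT against PROG, and 0, 4 and 108 for the interactions with DHT, MPA and PROG. Array weights gave 835, 471, 605 and 562 against vehicle, 238 for E2+DHT against E2, 19 for E2s+PROG against E2 and 388 against E2+PROG. They gave 196 for MPA against PROG, 1735 for DHT against MPA, 2783 for DHT against PROG, 105 for E2+DHT against E2+MPA and 692 against E2+PROG, and 2, 15 and 607 for the interactions.

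The stricter filter gave 6 for E2s+PROG against E2, 141 against E2+PROG, 20 for DHT against MPA, 26 for E2+DHT against E2+MPA, and 0, 3 and 118 for the interactions. Log2 and quantile scaling gave 2 for PROG. The authors' processed values gave 2 for the interaction with MPA. For the interaction with DHT the count was 0 with log2 and quantile scaling, the authors' values, and the mean of probes, where limma had 659, 653 and 649 genes at an unadjusted p under 0.05.

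With the run as a block the counts were 1516 for E2, 1010 for DHT, 523 for E2+MPA against E2, 87 for MPA against PROG, and 0, 80 and 435 for the interactions. Leaving out vehicle replicate 1 as well gave 378 for E2, 4 for PROG, 221, 917 and 521 for E2+DHT, E2+MPA and E2+PROG against E2, and 22 for E2s+PROG against E2 and 322 against E2+PROG. It gave 106 for MPA against PROG, 551 for E2+MPA against E2+PROG, 107 for E2+DHT against E2+MPA and 0 for the interaction with DHT. As 6 runs the columns gave 124 for MPA, 1 for PROG, 103 for DHT against PROG, and 0, 3 and 94 for the interactions.

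In the 24 arrays outside the run the counts were 1275 for E2, 694 for MPA, 727 for PROG, 84, 88 and 133 for E2+DHT, E2+MPA and E2+PROG against E2, and 5 and 109 for E2s+PROG against E2 and E2+PROG. They were 13 for DHT against MPA, 28 for DHT against PROG, 91 for E2+MPA against E2+PROG, 33 and 237 for E2+DHT against E2+MPA and E2+PROG, and 1 for the interaction with MPA. Without vehicle replicate 1 as well they were 486 for E2, 190 for DHT, 32 for PROG, 122 and 188 for E2+MPA and E2+PROG against E2, and 7 for E2s+PROG against E2. They were 95 for MPA against PROG, 23 and 51 for DHT against MPA and PROG, 136 for E2+MPA against E2+PROG, and 2 and 1 for the interactions with DHT and MPA. In the 12 arrays of the run they were 30 for E2, 18 for DHT, 14, 588 and 89 for E2+DHT, E2+MPA and E2+PROG against E2, and 0 and 41 for E2s+PROG against E2 and E2+PROG. They were 526 for E2+MPA against E2+PROG, 65 for E2+DHT against E2+PROG and 0 for the interaction with DHT, and the run gives no value where MPA or PROG alone is compared.

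Leaving out each array in turn gave 156 to 555 genes for E2, 164 to 366 for DHT, 119 to 1692 for MPA and 1 to 943 for PROG, highest without vehicle replicate 2 for E2, MPA and PROG. It gave 156 to 733 for E2+MPA against E2, 137 to 191 for E2s+PROG against E2+PROG, 30 to 77 for DHT against MPA, 110 to 771 for DHT against PROG and 192 to 406 for E2+MPA against E2+PROG. For the interactions it gave 0 to 2 for DHT, 3 to 955 for MPA and 116 to 393 for PROG. The other 6 counts stayed within 1.5 times.

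Genes shared against separate vehicle arrays numbered 40 to 59 for DHT and MPA, 0 to 14 for DHT and PROG, 1 to 20 for MPA and PROG, 5 to 12 for E2 and DHT, 8 to 20 for E2 and MPA and 1 to 9 for E2 and PROG. The block gave 212 for DHT and MPA, 357 for E2 and DHT and 119 for E2 and MPA. With separate E2 arrays DHT moved 1 to 4 of the E2-responsive genes back and 1 to 7 further, MPA 13 to 29 back, and progesterone 15 to 27 back and 9 to 15 further. The block gave 23 back and 17 further for DHT, 163 and 23 for MPA and 87 and 43 for progesterone.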

Other observations

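All 18 tests of other splits given here were chosen only after the counts were seen.

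SERPINA3, which encodes a secreted inhibitor of proteases, was singled out after its values were seen. Its log2 signal was 7.43 ± 0.79 in vehicle, 7.52 ± 0.08 with DHT, 8.83 ± 0.27 with PROG, 9.21 ± 0.23 with MPA and 9.43 ± 0.09 with E2 (SD, n = 4). With E2 present it was 9.43 ± 0.26 with DHT, 10.79 ± 0.32 with MPA and 12.57 ± 0.21 with PROG, and 10.38 ± 0.10 in E2s+PROG (SD, n = 4). The rise with E2 had an adjusted p of 2.87e-07 and that with MPA one of 4.37e-06, while DHT differed from vehicle by 0.09 with an adjusted p of 0.917. Vehicle replicate 1 lay at 8.61 and the other vehicle arrays at 6.96 to 7.17, against 7.47 to 7.64 with DHT. The small difference with DHT thus rests on that vehicle array and does not show that DHT left SERPINA3 unchanged.

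Other splits of the same 8 arrays into groups of 4 numbered 35 for each comparison, the real one included. As many genes came from 1 split, the real one, in DHT (293, highest other 36), MPA (229, 3) and PROG (7, 1) against vehicle, in E2+DHT (132, 1) and E2s+PROG (11, 0) against E2, and in E2s+PROG against E2+PROG (212, 1). The same held for MPA against PROG (56, 0), DHT against MPA (38, 1), DHT against PROG (168, 1) and E2+DHT against E2+PROG (401, 1). For these the share was 1 of 35, or 0.0286, the smallest that such splits can give. That argues against chance, without a correction for the number of tests. The 7 genes of PROG rest on few arrays all the same, as without vehicle replicate 3 the count was 1, no more than the highest other split gave. By the count alone chance cannot be excluded where 2 of the 35 splits gave as many genes, for E2 (227, highest other 1081), E2+MPA (261, 1922) and E2+PROG (306, 1304), and E2+MPA against E2+PROG (296, 1940), nor for E2+DHT against E2+MPA, where 5 did (64, 351). Of 100 splits drawn for an interaction, 8 gave as many genes for DHT (1, highest other 2592), 6 for MPA (8, 1283) and 2 for PROG (188, 250). These draws shuffled all groups of the interaction, which also undoes the effects of E2 and of the second steroid. They cannot decide whether an interaction alone is chance, so chance is not excluded for any of the interactions. Splits with several times the real count point to a structure of the samples, and the highest other split for E2, E2+MPA, E2+PROG and E2+MPA against E2+PROG parted the 4 arrays that lie in the run or are vehicle replicate 1 from the other 4. For these 4 comparisons the second split follows that structure, so it says little against single genes such as PDZK1 with E2 (adjusted p 3.35e-23) or the estrogen-induced list, with 21 genes higher and 0 lower. For E2+DHT against E2+MPA chance stays open for the count of 64 genes and not for UGT2B28, which differed by 3.16 (adjusted p 9.68e-16) and passed in 23 of 23 alternatives, beside the conjugation list at an adjusted p of 1.74e-10. With the run of columns as a block these comparisons had 1516, 523, 405, 400 and 81 genes, and the interactions with DHT and MPA 0 and 80.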
